A study of Rattus norvegicus with 26 samples.

How the data were processed

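Tissue punches of the RVLM were taken from 26 male rats of 3 ages, and total RNA was treated with DNase, per the labels' protocols. Per the labels' protocols, 50 ng of RNA per animal was reverse transcribed, preamplified with a primer mix for the pathway and run by SYBR Green qPCR on a rat GABA and glutamate array of 96 wells. The authors deposited threshold cycles (Ct) for 96 wells and 26 animals, per the file headers, with no normalization. They also deposited a table of linear fold changes, ratios of one age group to another, per the file headers. How these ratios were normalized is not given in the sources used here. A search over all subsets of the 5 reference wells found that ratios of group means of 2 to the power of minus delta-Ct, with the geometric mean Ct of H02, H03 and H05 as reference and all 26 animals, returned the deposited values for 79 wells with a root mean square log2 error of 2.26e-15. The table has no value for 5 array wells. The design text gives 8 aged animals, while the labels give 10, and the deposited ratios rest on all 10.

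Groups, sets and weights were taken from the labels of each sample. Replicate numbers name separate animals. The smallest root mean square Ct difference between any 2 plates was 0.407, so no plate was a copy of another. The files name wells by position only. The roles of the last row were taken from the standard layout of this product line, together with the values: H01 to H05 reference genes, H06 genomic DNA control, H07 to H09 reverse transcription control and H10 to H12 PCR control. No gene was assigned to any position. The tests of gene lists could for that reason not be run, and the rule for named genes, up to 30 per comparison by size of change or by smallest p, was cut to 2 wells with the largest falls past the threshold and 2 wells above 0 with the smallest p in the comparisons without a call. Well B11 was added after its values were seen.

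A Ct above 35, or missing, was set to 35. This applied to 4 values above the limit and 4 without a Ct among 2184. Wells were tested if a share of at least 0.5 of the animals of 1 group had a Ct under 35, which kept all 84. Log2 relative expression was the arithmetic mean Ct of the 5 reference wells minus the Ct of the well, and a log2 fold change is minus delta-delta-Ct. It assumes a doubling per cycle. Wells were tested with limma 3.58.1 in R 4.3.3, in 1 fit of all animals with age groups and set as terms, moderated with eBayes, two-sided, with Benjamini-Hochberg adjustment over 84 wells and a threshold of 0.05. The design, the alternatives and the naming rule were fixed before the data were examined. A moderated F test covered the 3 ages and the age by set interaction. Single values, such as the array mean, were compared by exact two-sided permutation tests within sets, which enumerate every regrouping that keeps group sizes in each set. Raw Ct of the reference wells was tested by exact permutation without set. Differences with a standard error and 95% bounds came from a linear fit with set as a term. For a reference well against the other 4, the within-set difference of the permutation test is given with the SE of that fit. The number of plates, 8 to 10 per group, limits the precision, and each well was measured on 1 plate per animal.

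The procedure was tested on simulated data in which whole residual vectors were moved between animals of a set and 20 of 84 wells were lowered. For middle-aged against young, 63.3% of wells lowered by 1 on the log2 scale were recovered over 100 draws and 15.1% of those lowered by 0.5. For aged against young, 68.4% and 17.0% were recovered. With no well lowered, 2 and 3 of the 100 draws made any call. Moving residuals between animals gives the groups the same spread on average, while the real array mean had an SD of 0.58 in middle-aged, 0.32 in young and 0.30 in aged animals. The draws therefore do not cover false calls from unequal spread, nor a shift of the whole array. Residuals of the real wells were correlated, with a median of 0.413 between wells, so wells are not independent.

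Alternatives covered leaving out each reference well, the array mean as reference, H02, H03 and H05 as reference, the Ct limit, the filter, the set term, each set alone, the replicate number as a block, only the groups compared, each animal left out, array weights, robust moderation and exact permutation tests per well on log and linear scales. Single reference wells, raw Ct and combinations with H02, H03 and H05 were added after the data were seen.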

Results

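The rostral ventrolateral medulla (RVLM) is a brainstem region whose neurons drive sympathetic outflow to the heart and blood vessels, under glutamatergic excitation and GABAergic inhibition. Its RNA was measured in 26 male Fischer 344 rats, an inbred strain widely used in ageing research. There were 8 young animals (3 to 5 months), 8 middle-aged animals (12 to 14 months) and 10 aged animals (22 to 26 months). The titles placed 5 animals of each age in set 1, and 3 young, 3 middle-aged and 5 aged animals in set 2. Body weight was 302 ± 17.2 g (SD, n = 8) in young, 438 ± 38.3 g (SD, n = 8) in middle-aged and 449 ± 43.1 g (SD, n = 10) in aged animals. Each animal had its own qPCR plate with 84 wells for genes of GABA and glutamate neurotransmission. The wells are identified by plate position alone and the files pair no position with a gene, so the array is described as a whole and by classes of wells.

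The threshold cycle (Ct) falls by about 1 for each doubling of template, so a low Ct marks an abundant transcript. Mean Ct per well ranged from 16.6 to 31.8 with a median of 22.4, and 4 of the 2184 array values had no Ct. Relative expression was the mean Ct of 5 reference wells minus the Ct of the well, on a log2 scale. Set 2 differed from set 1 over all ages. Its array Ct was higher by 1.67 ± 0.25 (SE) and its reference Ct by 1.23 ± 0.16 (SE), which left array expression at -0.43 ± 0.14 (SE) on the log2 scale relative to set 1. The reverse transcription control Ct went the other way, at -1.20 ± 0.23 (SE) relative to set 1. Set was a term in the limma fits unless stated otherwise.

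The first comparison asked how expression in middle-aged animals stood against that in young animals. In limma with Benjamini-Hochberg adjustment, 39 of 84 wells were lower in middle-aged animals and 0 were higher, with 49 wells at an unadjusted p under 0.05. The falls of those 39 wells ran from -0.37 to -1.06 on the log2 scale, and the median over all 84 wells was -0.56, a fold of 0.679. Fold changes were below 0 in 77 of the 84 wells. The well mean over the array was -5.16 ± 0.32 (SD, n = 8) in young and -5.69 ± 0.58 (SD, n = 8) in middle-aged animals. The within-set difference of -0.53 had an exact two-sided permutation p of 0.0147 (adjusted p = 0.0372 over 3 comparisons), and 7 of 8 middle-aged animals lay below the young mean of their set.

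Lower expression in middle-aged animals was spread over abundant and scarce transcripts. Among the 28 wells with the lowest Ct (16.6 to 20.9), 16 fell and the median log2 fold change was -0.56. Among the 28 wells of middle Ct (up to 23.9), 17 fell, with a median of -0.60. Among the 28 wells with the highest Ct (24.0 to 31.8), 6 fell and the median was -0.41, at a median standard error of 0.45 against 0.21 in the wells of lowest Ct. The largest falls past the threshold were in well A04, at -1.06 ± 0.36 (SE; limma adjusted p = 0.0203), and well A09, at -1.03 ± 0.30 (SE; limma adjusted p = 0.0140). Of the 8 middle-aged animals, 6 lay below the young mean of their set in A04 and 7 in A09. Mean relative expression of A04 was -7.92 ± 0.45 (SD, n = 8) in young and -8.98 ± 1.26 (SD, n = 8) in middle-aged animals, and that of A09 was -5.82 ± 0.35 (SD, n = 8) and -6.85 ± 0.98 (SD, n = 8).

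Middle-aged replicate 8 stood apart with an array mean of -6.98; without it limma called 28 lower wells and the array mean differed by -0.37 (exact permutation p = 0.0278). The count differed between fits and between reference wells. With only young and middle-aged animals in the fit, limma called 0 wells (39 at an unadjusted p under 0.05), exact permutation tests without set called 5, limma without the set term called 11, and centring each plate on its array mean left 1. Against single reference wells limma called 0 wells with H01 (6 at an unadjusted p under 0.05), 63 with H02, 21 with H03, 0 with H04 (30 at an unadjusted p under 0.05) and 60 with H05, and the array mean differed by -0.014 against H01 (exact permutation p = 0.944) and by -0.39 against H04 (exact permutation p = 0.0690). Within sets, limma called 0 wells in set 1 (17 at an unadjusted p under 0.05, median -0.37) and 42 lower wells in set 2 (median -1.05). The array mean differed by -0.35 in set 1 (exact permutation p = 0.135) and by -0.83 in set 2 (exact permutation p = 0.1, the smallest that 3 against 3 animals allow).

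**Figure D1:**
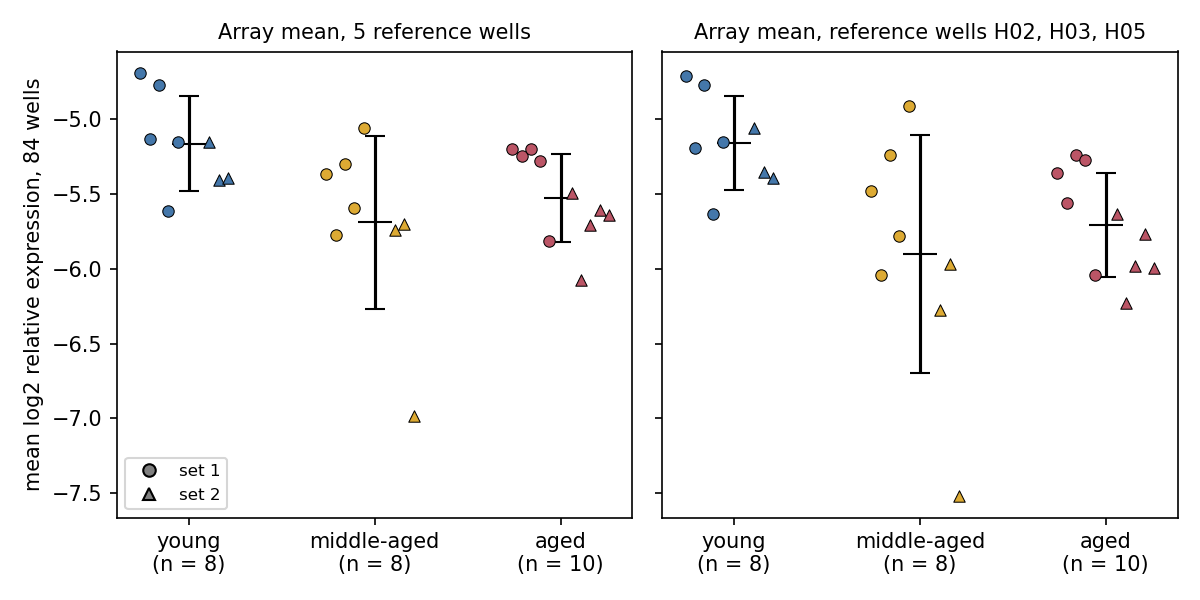
Mean log2 relative expression over the 84 array wells (vertical axis) for each animal by age group, with circles for set 1, triangles for set 2, and bars for the group mean and SD. With 5 reference wells (left) the group means were -5.16, -5.69 and -5.53 in young, middle-aged and aged animals, and with H02, H03 and H05 (right) they were -5.16, -5.90 and -5.71; the lowest middle-aged animal lay at -6.98 on the left.

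The second comparison asked how the oldest animals stood against the same young animals, whose chance deviations both comparisons share. The array as a whole was lower in aged animals, at -5.53 ± 0.30 (SD, n = 10) against -5.16 ± 0.32 (SD, n = 8) in young animals. The within-set difference was -0.32 with an exact two-sided permutation p of 0.0248 (adjusted p = 0.0372), and all 10 aged animals lay below the young mean of their set. The linear fit was less clear: its difference was -0.31, with a 95% interval from -0.65 to 0.035 that included 0. This fit and the main limma fit pool the spread of all age groups, and the array mean had an SD of 0.58 in middle-aged animals. Fold changes were below 0 in 74 of 84 wells, with a median of -0.32 and a fold of 0.801. No single well passed: limma called 0 of 84 wells, with 14 at an unadjusted p under 0.05 and a smallest adjusted p of 0.259. With only young and aged animals in the fit, limma again called 0 wells, with 29 at an unadjusted p under 0.05. The same setting for middle-aged against young also gave 0 wells (39 at an unadjusted p under 0.05). The main counts, 39 lower wells in middle-aged and 0 in aged animals, thus do not by themselves show that these ages differ. How far the pooled spread moved either count was not tested. The array-mean test was chosen after the wells had been seen to move together.

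The classes of abundance gave similar medians in aged animals. These were -0.27 in the 28 wells of lowest Ct, -0.33 in those of middle Ct and -0.36 in those of highest Ct. Well A04 had a log2 fold change of -0.56 ± 0.34 (SE; limma adjusted p = 0.328) and A09 one of -0.45 ± 0.29 (SE; limma adjusted p = 0.342). Well C06, a scarce transcript with a mean Ct of 29.3 in young animals, had the highest value on the array, 0.63 ± 0.28 (SE; limma adjusted p = 0.269). Relative to the array mean of each plate, C06 rose by 0.93 ± 0.21 (SE; limma adjusted p = 0.0118), with all 10 aged animals above the young mean of their set. In middle-aged against young animals that value was 0.68 ± 0.22 (SE; limma adjusted p = 0.0984), with 7 of 8 animals above, against 0.15 relative to the 5 reference wells. A value relative to the array mean also rises when the array mean falls.

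The array-wide difference in aged animals depended in part on reference wells H02 and H04. The array mean differed by -0.19 without H02 (exact permutation p = 0.133) and by -0.42 without H04 (exact permutation p = 0.00510). Against H04 alone the difference was 0.041 (exact permutation p = 0.826). Array quality weights moved the limma count from 0 to 26 wells (25 lower, 1 higher), and exact permutation tests without set on linear values relative to H02, H03 and H05 gave 43 lower wells. Within sets the array mean differed by -0.28 in set 1 (exact permutation p = 0.167) and -0.39 in set 2 (exact permutation p = 0.0357). Without young replicate 6 the pooled difference was -0.29 (exact permutation p = 0.0578).

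**Figure D2:**
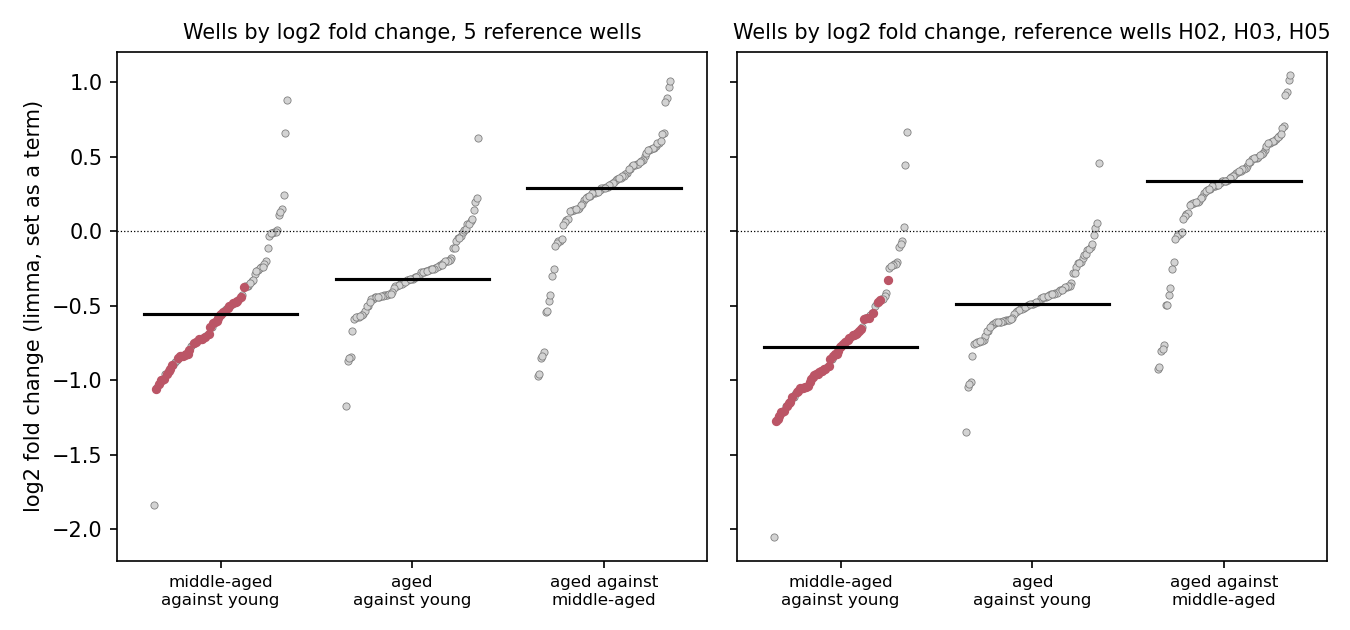
Log2 fold change from limma (vertical axis) of each of the 84 array wells, ordered by value within each comparison, with 5 reference wells (left) and with H02, H03 and H05 (right). Red points passed an adjusted p of 0.05, grey points did not, and black lines are medians; 39 wells passed on the left and 54 on the right, all lower in middle-aged than in young animals.

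The third comparison set aged against middle-aged animals. No well passed in limma (0 of 84), with 10 wells at an unadjusted p under 0.05 and a smallest adjusted p of 0.323. Fold changes lay above 0 in 68 wells, with a median of 0.29. The array mean differed by 0.23 (exact permutation p = 0.213), so no difference was established. The 95% interval of the fitted difference ran from -0.13 to 0.56. Well F03 had the smallest p among the wells above 0, at 0.87 ± 0.30 (SE; limma adjusted p = 0.323). Without middle-aged replicate 8 the array mean difference was 0.05 (exact permutation p = 0.676) and the F03 value 0.52. Array quality weights gave 39 wells past the threshold, 36 of them higher in aged animals and 3 lower.

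Across the 3 ages, the moderated F test of limma called 18 wells, all of them among the 39 that were lower in middle-aged than in young animals. With H02, H03 and H05 it called 40, and leaving out single animals moved the count between 0 and 39. The test of an age effect that differs between sets called 1 well, with 20 at an unadjusted p under 0.05.

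The reference and control wells were compared by age because a reference that moves shifts every well. Raw Ct of the 5 reference wells gave 0 of 15 comparisons past the threshold in exact permutation tests, with 0 at an unadjusted p under 0.05. Those tests were planned without set; within sets 0 of 15 passed and 1 was at an unadjusted p under 0.05, H02 in aged against young, at -0.38 (exact permutation p = 0.00638, adjusted p = 0.0957). Set against the mean of the other 4 within sets, a measure chosen after the result was seen, H02 was lower in Ct by -0.66 ± 0.14 (SE) in aged than in young animals (exact permutation p = 0.000142, adjusted p = 0.00213). There H04 was higher by 0.46 ± 0.17 (SE, exact permutation p = 0.0149, adjusted p = 0.0749). H03 was higher by 0.17 ± 0.11 (SE, exact permutation p = 0.0349, adjusted p = 0.0749). H01 was at 0.23 and H05 at -0.20 (exact permutation p = 0.205 and 0.0592). For middle-aged against young the same measure gave 0.64 ± 0.22 (SE) for H01, -0.44 ± 0.15 (SE) for H02 and -0.35 ± 0.11 (SE) for H05. Their exact permutation p was 0.0317, 0.0198 and 0.0226 (adjusted p = 0.0749 for each). H03 was at -0.015 and H04 at 0.17 (exact permutation p = 0.906 and 0.294). The reference wells thus may not have been stable against each other in that comparison either. Mean Ct of H02 was 17.2 ± 0.617 (SD, n = 8) in young and 17.0 ± 0.586 (SD, n = 10) in aged animals, while that of H04 was 19.2 ± 0.722 (SD, n = 8) and 19.8 ± 0.711 (SD, n = 10). Mean Ct of the reverse transcription control was 25.5 ± 0.753 (SD, n = 8) in young, 25.3 ± 1.09 (SD, n = 8) in middle-aged and 25.1 ± 0.655 (SD, n = 10) in aged animals. The PCR control stood at 21.2 ± 0.171 (SD, n = 8), 21.4 ± 0.504 (SD, n = 8) and 21.2 ± 0.304 (SD, n = 10). In set 2 alone, the reverse transcription control stood at 25.03 ± 0.088 (SD, n = 3) in young animals. It was 24.09 ± 0.277 (SD, n = 3) in middle-aged and 24.63 ± 0.216 (SD, n = 5) in aged animals. The highest middle-aged value there, 24.36, lay below the lowest young value, 24.93. In set 1, young and middle-aged animals stood at 25.81 ± 0.837 and 25.98 ± 0.613 (SD, n = 5 each). Why the sets differed here was not tested.

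**Figure D3:**
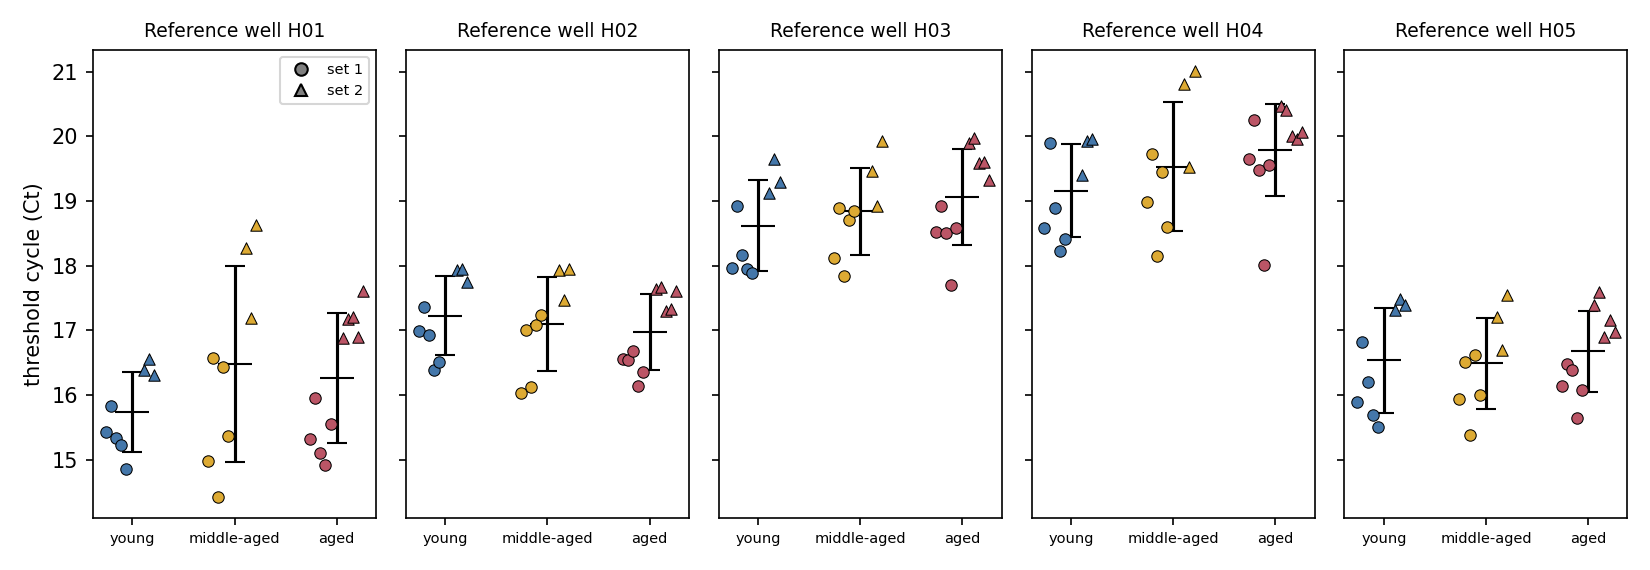
Threshold cycle (vertical axis) of the 5 reference wells for each animal by age group, with circles for set 1, triangles for set 2, and bars for the group mean and SD. Set 2 sits above set 1 in each panel as a whole. In young, middle-aged and aged animals, H01 has group means of 15.7, 16.5 and 16.3, H02 of 17.2, 17.1 and 17.0, and H04 of 19.2, 19.5 and 19.8.

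The authors' deposited table of fold changes gave values for 79 of the 84 wells. Of these, 77 wells were below 1 in the authors' deposited table for middle-aged over young (median fold 0.642) and 76 for aged over young (median fold 0.687). For aged over middle-aged, the authors' deposited table had 27 wells below 1 and 52 above, with a median fold of 1.09. The authors' deposited table listed A04 at 0.579 in each older group over young, and A09 at 0.522 in middle-aged and 0.628 in aged animals. The deposited folds were recovered as ratios of group means on the linear scale, while limma compares means of log2 values. Exact permutation tests without set on the linear scale, with H02, H03 and H05, called more wells in aged than in middle-aged animals, each against young. On log2 values with these reference wells, limma called 54 wells lower in middle-aged than in young animals, including all 39 of the main count. It called 0 in aged against young (27 at an unadjusted p under 0.05, smallest adjusted p 0.1). The array mean then differed by -0.74 in middle-aged (exact permutation p = 0.0103) and by -0.51 in aged animals (exact permutation p = 0.00312) against young.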

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

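The tests of single animals, reference wells and control wells in this part were chosen after the results were seen, while those of other splits of the animals, genomic DNA and scarce wells were set before their results were seen. Of 57 pairs of a group and a measure, 7 held an animal far from the rest of its group, and chance gives about 1 in 20.

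Array wells were lower together in middle-aged and aged than in young animals. A fall in the Ct of the reference wells as the whole cause is argued against by their raw Ct only if RNA input was equal. The lower 95% bound of the difference was -0.19 in middle-aged and -0.26 in aged animals, against fitted array shifts of -0.53 and -0.31. Equal template was not measured. Reference mean Ct was 18.57 in middle-aged and 18.16 in young animals of set 2, and 17.16 and 17.04 in set 1. Less template in the older animals could hide a fall in reference Ct. Single reference wells do differ: the aged result is lost without H02 (-0.19, exact permutation p = 0.133), and the middle-aged difference is -0.014 against H01 alone (exact permutation p = 0.944) and -0.39 against H04 alone (exact permutation p = 0.0690). For the reverse transcription and PCR control Ct, upper 95% bounds of the difference from young were 0.348 and 0.477 on the middle-aged plates. On the aged plates they were 0.325 and 0.298. These bounds cannot decide whether weaker amplification caused the shifts. A loss shared by all wells of a plate raises array and reference Ct alike and cancels in relative expression. A loss in some wells only is not measured by the control wells. The control bounds pool the sets, while in set 2 the reverse transcription control Ct was lower in middle-aged than in young animals (24.09 against 25.03). How much of either fall rests on the choice of reference wells or on amplification stays open. So do the amount of template, RNA quality, preamplification and the cell content of the punches, which were not measured, beside age itself.

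Middle-aged replicate 8 had an array mean of -6.98, against -5.77 for the next animal, and was also apart in A04 at -11.55 (next -9.32) and F03 at -9.11 (next -6.88). Its plate had the highest reference mean Ct (19.01) and the lowest reverse transcription control Ct (23.81) of all 26 animals. Its PCR control Ct was 21.44. Why this animal stood apart was not tested. Without it the middle-aged difference was -0.37 (exact permutation p = 0.0278) and limma called 28 wells, so this animal alone does not account for the array-wide fall. The larger deficit in set 2 is a separate matter: without that animal the set 2 difference was -0.41, against -0.35 ± 0.21 (SE) in set 1, but with H02, H03 and H05 it was -0.85 against -0.40 ± 0.26 (SE). Whether this animal explains the set difference cannot be told apart from a real difference between sets, because 2 middle-aged animals remain in set 2. The set difference itself was -0.48 ± 0.48 (SE), and -0.92 ± 0.55 (SE) with H02, H03 and H05.

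Other splits of the animals within sets show how often a regrouping reaches a count, against a share of 0.05 set beforehand and without adjustment over the counts. For middle-aged against young, 2 of 100 drawn splits, the real one included, called at least 39 wells, and the highest other split called 55. That lies under the share of 0.05. But 100 draws estimate the share coarsely and another split called more wells than the real one, so chance is made less likely and is not excluded. For the F test 1 of 100 splits, the real one, reached 18, the highest other being 10, which lies under the share of 0.05 too. For the age effect by set, 10 of 100 splits reached the real count of 1 and the highest other called 19, several times the real count, so chance cannot be excluded. Why a split called so many wells was not tested. For aged against young and aged against middle-aged the real count was 0, which all 100 splits reached, with 0 and 2 as the highest other counts.

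Well B11, singled out after its values were seen, was the 1 well whose age effect differed between sets (limma adjusted p = 0.0302). Middle-aged minus young was 0.76 in set 1 and -3.66 in set 2, and -2.63 in set 2 without middle-aged replicate 8. The call was lost without any 1 of 8 animals, where limma called 0 wells: young replicates 1, 4, 5, 7 and 8 and middle-aged replicates 1, 3 and 8. Well A09 had a low value of -6.60 in young replicate 4 (next -5.95). Reference well H04 had a low Ct of 18.0 in aged replicate 4 (next 19.5). PCR control wells had high Ct on 2 plates, 23.8 in H11 of middle-aged replicate 5 (next 21.5) and 27.7 in H12 of young replicate 5 (next 21.6).

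The genomic DNA control well gave a Ct on 9 of 26 plates, 3 young, 1 middle-aged and 5 aged, with 8 of the 9 in set 1. The Ct was under 35 on 5 plates and 31.7 at the lowest. Well C06 was higher relative to the array mean in aged than in young animals, by 0.93 ± 0.21 (SE), and in middle-aged animals by 0.68 ± 0.22 (SE; limma adjusted p = 0.0984). Part of either value is the fall of the array mean itself. The tests below concern aged against young. Genomic DNA is argued against by the difference of 0.90 ± 0.32 (SE) over the 5 young and 5 aged plates without a Ct in that control. A general rise of scarce wells is argued against by the 10 wells nearest in Ct (27.5 to 30.7), which had a median of -0.023 and a highest value of 0.53. A change in this transcript with age stays as a hypothesis, found and tested on the same plates. Relative to the 5 reference wells C06 was at 0.63 (limma adjusted p = 0.269) and passed with array quality weights (0.57, limma adjusted p = 0.0374), with adjusted p from 0.0118 to 0.892 over the settings tried.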

How the results depend on the processing

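Single reference wells, raw Ct and combinations with H02, H03 and H05, and every test of the array mean, were chosen after the data were seen; the cause of each change below was not tested unless stated. Tests of gene lists were not run, since wells carry no gene names, and the array mean has no value when it is itself the reference. Aged against young, limma called 0 wells in the main setting, 1 relative to the array mean, 26 with array weights, 53 with H02 alone, 14 with H02, H03 and H05 without middle-aged replicate 8, and 43 in exact permutation tests with those wells on the linear scale. Middle-aged against young, the count of 39 became 1 relative to the array mean, 11 without the set term, 0 in set 1 alone (fewer animals), 0 with only the 2 groups fitted, 5 in exact permutation tests on the log and 5 on the linear scale, 0 with H01 alone, 63 with H02 alone, 21 with H03 alone, 0 with H04 alone, 60 with H05 alone and 21 in exact tests with H02, H03 and H05 on the linear scale; left-out animals gave 28 to 50. Aged against middle-aged, array weights gave 39 in place of 0. The F test count of 18 became 33 without H01, 0 without H02, 0 without H05, 2 relative to the array mean, 40 with H02, H03 and H05, 0 without the set term, 0 in set 1, 9 in set 2, 11 with the replicate block, 55 with array weights, 0, 57, 0, 0 and 47 with H01, H02, H03, H04 and H05 alone, and 0 on raw Ct. Left-out animals gave F counts of 0 to 39: 0 without young replicates 1, 2, 3, 6, 7 or 8 or middle-aged replicates 2 or 4, 6 without middle-aged replicate 6 or 8, and 39 without young replicate 4 or middle-aged replicate 3 or 5. The count for age by set, 1, became 2 without H01, 2 without H04, 3 relative to the array mean, 2 with H02, H03 and H05, 9, 25, 0 and 20 with H01, H03, H04 and H05 alone, 0 on raw Ct and 0 with H02, H03 and H05 without middle-aged replicate 8; left-out animals gave 0 to 7, with 0 without young replicates 1, 4, 5, 7 or 8 or middle-aged replicates 1, 3 or 8, 2 without middle-aged replicates 5, 6 or 7 or aged replicate 10, and 7 without middle-aged replicate 4. The array mean difference, aged against young, of -0.32 became -0.19 without H02, -0.28 in set 1, -0.14 with H01, -0.18 with H03 and 0.041 with H04 alone, all with an exact permutation p above 0.05; left-out animals gave -0.40 to -0.26, past 0.05 but for young replicate 6 (-0.29). Middle-aged against young, -0.53 became -0.35 in set 1, -0.83 in set 2 (too few animals for a p under 0.1), -0.014 with H01, -0.39 with H04 alone and -0.76 on raw Ct, each with an exact permutation p above 0.05. Aged against middle-aged, 0.23 became -0.16 with H01 alone and 0.45 with H04 alone (exact permutation p = 0.0319). Replicate numbers do not pair the animals: 4 of 8 pairs correlated above 0.1 in each comparison, with their shared set left in. Within sets this held for 2 pairs in aged against young, 3 in middle-aged against young and 2 in aged against middle-aged. The replicate block gave 37 wells for middle-aged against young and 0 for the other comparisons. The Ct limit, the filters and robust moderation moved no count by more than 1.5 times. In simulated data for middle-aged against young, 15.1% of wells lowered by 0.5 on the log2 scale were recovered.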

Other observations

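Of the 2 hypotheses here, body weight was tested before its result was seen and the reference well was chosen after. Body weight may go with the array mean among animals of one age and set. Deviations from the group and set means gave r = -0.026 (permutation p = 0.904) and rho = -0.11 (permutation p = 0.625; adjusted p = 0.904 for each) over 26 animals, and r = -0.22 without the 2 animals farthest in weight, so no relation was seen. Reference well H01 may vary with the array wells, since against H01 alone the middle-aged difference was -0.014 (exact permutation p = 0.944). Deviations were taken with no shared reference, H01 relative to 1 of H02, H03 and H05 and the array relative to the other 2, over 26 animals. The 14 coefficients over all 26 animals were adjusted together, and those without the 2 farthest animals were not part of the adjustment. Relative to H02, r was 0.764 (permutation p = 0.000210, adjusted p = 0.00294) and rho 0.694 (permutation p = 0.00150, adjusted p = 0.0105), and r was 0.717 without the 2 farthest animals. Relative to H05, r was 0.418 (permutation p = 0.0614, adjusted p = 0.131) and rho 0.435 (permutation p = 0.0479, adjusted p = 0.131), with r = 0.429 without the 2 farthest. Relative to H03, r was 0.308 (permutation p = 0.133, adjusted p = 0.202) and rho 0.231 (permutation p = 0.299, adjusted p = 0.349), with r = 0.275 without the 2 farthest. The 3 pairings differ in whether they pass, so the hypothesis stays open. An earlier pairing with H04 gave r = 0.090 (permutation p = 0.640) and rho = 0.099 (permutation p = 0.640), and r = 0.118 without the 2 farthest and goes against the hypothesis, unless H04 varies with the array too. H04 relative to H02, H03 and H05 gave r of 0.433, 0.338 and 0.408 with the array, none past the threshold (adjusted p = 0.131, 0.227 and 0.131), so this was not settled either.

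After age and set, the first component of the residuals of relative expression held 39.9% of their variance, and 81 of 84 wells correlated above 0 with the mean of the others. Every well of a plate has the same reference mean subtracted, which by itself makes such residuals correlate, so these values do not show that the transcripts varied together.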
